A study of Rattus norvegicus with 12 samples.

How the data were processed

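The samples were 12 RNA extracts of rat colonic mucosa and submucosa, each measured on its own array, in 4 groups of 3. Per the labels' protocols, 2 µg of total RNA per sample was extended with a poly(A) tail, ligated to a tag, hybridized overnight to a microfluidic array and stained with Cy5. The deposited scanner output holds the median pixel intensity of each spot on a linear scale, per the file headers. It was neither background-corrected nor scaled between arrays, and it gives no local background, slide or scan date. A second deposited table holds the authors' processed intensity of each probe: background-subtracted, averaged over spots and rescaled between arrays, by a method not given in the sources used here. Its values are linear and not negative. The factor by which each array was rescaled stays unknown, as does whether arrays were centred on a common level. Its rank correlation with the scanner values of the same array was between 0.982 and 0.999. Its column medians were 74.5, 56.5 and 57 for the arrays of Ctl+Ctl, 71.5, 55 and 62.5 for Ctl+AI, 50, 56 and 58 for NI+Ctl, and 49.5, 55 and 61.5 for NI+AI. That table served only as an alternative.

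Each array had 3968 spots: 2908 of the 727 rat microRNA probes in 4 spots each, 748 empty, 20 background, 268 of 43 spike-in control probes and 24 of 6 probes of 5S ribosomal RNA. No 2 arrays held identical values. Scanner intensities were corrected by normexp over all spots with an offset of 50, put on the log2 scale, averaged over the 4 spots and quantile normalized over the 727 probes in limma 3.58.1 with R 4.3.3. The labels were read with jsonlite 2.0.0. A probe counted as detected on an array where its mean signal exceeded the 95th percentile of that array's empty spots. Probes detected on every array of at least 1 group were tested, 389 in all, of which 265 were detected on all 12 arrays. Between 42.9% and 71.0% of the probes were detected per array. The median of the empty spots lay between 32.9 and 308, with the highest values on Ctl+Ctl array 1 (308), Ctl+AI array 1 (224) and Ctl+AI array 2 (128). The variation between the 4 spots of a probe was between 7.47% and 10.9% (median coefficient of variation per array). For a probe detected on no array of a group only a bound is given: the mean of the brighter group was set against the mean, over the arrays of the dimmer group, of the higher of the lowest detected signal and the probe's own signal, and written as at least N-fold. In a main effect this was done for the arrays of the undetected group, and the groups of each side were then averaged.

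All 12 arrays entered 1 linear model with the 4 groups (lmFit and eBayes, 8 residual and 2.57 prior degrees of freedom). Tested were the adult and the neonatal main effect of TNBS, their interaction and 5 differences between groups. P-values are two-sided and adjusted by Benjamini and Hochberg over the 389 probes, with a threshold of 0.05, and every adjusted p of a microRNA comes from limma. Comparisons that use the same arrays are not independent, and no overlap between the calls of 2 of them is given. Errors of log2 differences are standard errors, and those of group means are standard deviations. The study design, the tests, the gene lists and the alternatives were chosen before the data were examined, unless said otherwise. The 14 gene lists were the miR-200 family, intestinal epithelium, inflammation-associated, leukocytes, erythrocytes, smooth muscle and mesenchyme, endothelium, miR-29 family, let-7 family, miR-17-92 and paralogs, microRNAs described as acting on Cdh1 mRNA, those described as acting on epithelial permeability, neurons and hypoxia. Some microRNAs stand in more than 1 list, and 75 listed members were on the array. Lists with at least 3 tested members, 11 in all, were tested with camera (preset correlation 0.01, and with an estimated correlation as an alternative), two-sided and adjusted over the 11 lists. The erythrocyte, endothelial and hypoxia lists had fewer and are given by member.

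Named for each comparison were the 8 largest rises and 8 largest falls among the probes past the threshold, or, where fewer than 5 passed, the 6 probes with the smallest unadjusted p, said not to pass. Added were a panel of 14 microRNAs of inflammation, leukocytes, epithelium and muscle, given partly through their lists, and from each list up to 4 called members, or the 2 with the smallest p, not all of which are printed. Whatever else is named was chosen after its values were seen. Names are those of the array. The files name no genome build, so no coordinates are given. For neighbours in the genome, the probes were matched to the GRCr8 annotation: 688 to 1 gene, 35 to several and 4 to none. Probes whose targets differ by at most 2 mismatches over at least 18 bases count as near-identical.

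Alternatives were cyclic loess, scaling by the 75th percentile of the probes detected on all arrays, no normalization between arrays, the deposited value table on the scale of log2(value + 50), no background correction, subtraction with a floor, an offset of 16, no filter on dim probes, only probes detected on all 12 arrays, a trended robust fit, array weights, a fit to only the groups compared, and leaving out each array in turn. Chosen after seeing the data were the array's spike-in mismatch ratio as a covariate, leaving out Ctl+Ctl array 1 and Ctl+AI array 1, removing each array's loess trend with GC content (span 0.75), and genomic clusters as lists. The code was tested on simulated data built from the 389 probes, in 20 runs with 20 changed probes per size. For NI+AI against Ctl+Ctl it recovered 37.8%, 77.5% and 96% of changes of 0.5, 1 and 2 on the log2 scale, with 4.51% false among the calls. For the adult main effect it recovered 59.5%, 89.8% and 98.5%, with 5.08% false. In the simulation of NI+AI against Ctl+Ctl, a list of 8 probes shifted by 0.5 was called in 20 of 20 runs and a random list in 0 of 20. The simulated probes varied independently, with no correlation between microRNAs and no differences between arrays. The shares of false calls therefore need not hold for the real arrays and lists.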

Results

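MicroRNAs were measured in the colonic mucosa and submucosa of male Sprague Dawley rats, an outbred laboratory strain, on 12 single-colour (Cy5) microarrays. The study asked whether inflammation of the newborn colon leaves a mark on the barrier of the adult gut and on its E-cadherin, the adhesion protein encoded by Cdh1. Inflammation was induced with trinitrobenzene sulfonic acid (TNBS), a hapten that provokes colitis when it is given into the lumen with ethanol. Pups received 130 mg/kg TNBS in 200 µl saline with 10% ethanol on postnatal day 10, or saline. Adults received 65 mg/kg TNBS in 250 µl with 40% ethanol 6 to 8 weeks later, or saline, and tissue was taken 7 days after that. The adult dose is that of the labels' protocol, and the titles of the adult TNBS samples carry a code with another number, T68, whose meaning is not given. The 4 groups had 3 arrays each: saline at both ages (Ctl+Ctl), saline then TNBS (Ctl+AI), TNBS then saline (NI+Ctl) and TNBS at both ages (NI+AI). Since the saline of the sham groups held no ethanol, every TNBS effect given here is that of TNBS together with its ethanol vehicle. MicroRNAs are named as on the array, without the prefix rno-. Pairs with near-identical sequences, such as miR-133a-3p and miR-133b-3p, miR-29a-3p and miR-29c-3p, or let-7e-5p and let-7a-5p, can bind each other's probes, so which member of such a pair gave a signal is uncertain.

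Each array carried 727 rat microRNA probes in 4 spots each, and between 312 (Ctl+Ctl array 1) and 516 (NI+Ctl array 1) of them lay above the empty spots of the same array. In Ctl+Ctl the microRNAs miR-194-5p and miR-192-5p of the intestinal epithelium had normalized log2 intensities of 15.01 (on each of the 3 arrays) and 14.78 ± 0.03 (SD, n = 3). The smooth muscle microRNA miR-145-5p stood at 14.67 ± 0.20 (n = 3). Values of all tested probes correlated within groups with r between 0.952 and 0.987 and between groups with r between 0.929 and 0.991. The highest value joined arrays of different groups, Ctl+Ctl array 1 and Ctl+AI array 1. Next came Ctl+AI array 2 with Ctl+Ctl array 2 (0.990) and with Ctl+Ctl array 3 (0.989). On the first principal component (36.4% of the variance) Ctl+Ctl array 1 and Ctl+AI array 1 stood apart at −8.67 and −8.47. The next lowest value was −3.49 (Ctl+AI array 3). The 2 arrays that stood apart lie on the saline side of the neonatal main effect. A fit chosen after seeing the data left them out. The number of arrays limits the precision: the median standard error of a difference between 2 groups was 0.20 on the log2 scale. No title or file says more of the arrays' origin than a number per array, so p-values measure the spread between these 12 samples. Arrays of the TNBS-treated neonates also differed in probes that no rat supplied. Spike-in signals, here and below, were log2 scanner intensities without background correction or normalization between arrays, so array background enters them. The signal of 4 mismatched spike-in probes relative to their matched probes was −8.33 ± 0.76 on the log2 scale (SD, n = 6) on arrays of TNBS-treated neonates and −5.84 ± 1.36 (n = 6) on arrays of saline-treated neonates, a difference of −2.49 (exact permutation test over 924 splits, two-sided, p = 0.00216). Between the arrays of TNBS-treated and saline-treated adults the same difference was 0.16 (exact permutation test, two-sided, p = 0.866). The highest ratios, −4.10 on Ctl+Ctl array 1 and −4.31 on Ctl+AI array 1, came with the highest medians of the empty spots, 308 and 224.

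**Figure D1:**
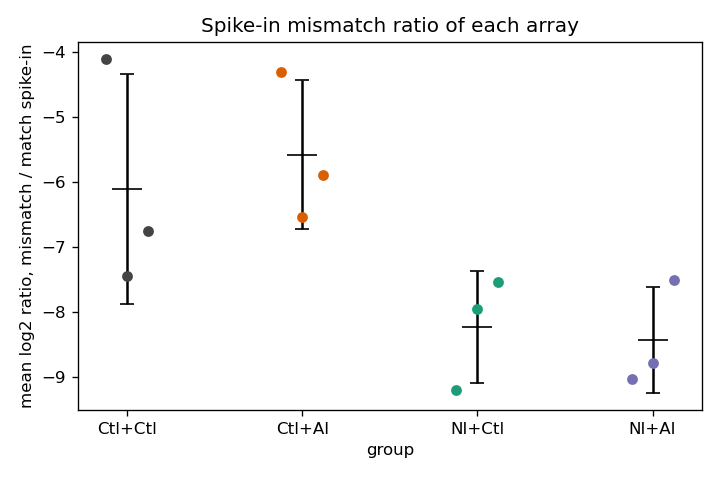
Mean log2 ratio of mismatched to matched spike-in signal of each array (y axis) by group (x axis); points are arrays, and bars give the mean ± SD of 3 arrays. The 6 arrays of TNBS-treated neonates lie between −9.19 and −7.50, and those of saline-treated neonates between −7.45 and −4.10.

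Adult TNBS, averaged over both neonatal treatments (6 arrays against 6), lowered microRNAs of muscle. miR-133a-3p, a microRNA of muscle cells, fell by 0.77 ± 0.12 on the log2 scale (SE; 1.71-fold, adjusted p = 0.0031), and miR-133b-3p fell by 0.59 ± 0.13 (1.51-fold, adjusted p = 0.019). miR-143-3p and miR-145-5p, which are made from the same transcript and keep smooth muscle in its contractile state, fell by 0.50 ± 0.11 (1.41-fold) and by 0.47 ± 0.12 (1.38-fold), with adjusted p of 0.016 and 0.041. Both lay near the upper end of the intensities, where quantile normalization limits how far values can differ. Some arrays of different groups there had the same value. In saline-treated adults miR-143-3p stood at 13.96 ± 0.18 (SD, n = 3) in Ctl+Ctl and 14.13 ± 0.14 (n = 3) in NI+Ctl, against 13.48 ± 0.23 (n = 3) in Ctl+AI and 13.61 ± 0.10 (n = 3) in NI+AI. Of the 8 tested members of the smooth muscle and mesenchyme list these 4 fell and 4 did not pass, 5 fell when adjusted over the list alone, and all 8 were lower, with a median of −0.48. Against the other probes the list was shifted down with camera's adjusted p = 3.7e-05, and adjusted p = 0.024 with an estimated correlation. Other falls were those of miR-653-3p by 0.82 ± 0.12, of miR-10a-5p by 0.78 ± 0.18, of miR-145-3p by 0.74 ± 0.15 and of miR-24-2-5p by 0.60 ± 0.16. miR-338-3p, above the empty spots on none of the NI+AI arrays, was at least 1.33-fold lower (adjusted p = 0.019). miR-23a-3p, described as acting on Cdh1 mRNA, fell by 0.43 ± 0.11 (adjusted p = 0.033).

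The rises after adult TNBS were led by microRNAs encoded in the imprinted region between Dlk1 and Dio3. miR-376c-3p rose by 0.87 ± 0.12 (SE; 1.83-fold, adjusted p = 0.0024), the largest rise, and miR-379-5p by 0.82 ± 0.13 (1.76-fold, adjusted p = 0.0034). On only 1 of the 3 Ctl+Ctl arrays did miR-379-5p lie above the empty spots. miR-434-3p and miR-541-5p of the same region rose by 0.78 ± 0.16 and 0.71 ± 0.15, and miR-136-3p, above the empty spots on none of the Ctl+Ctl arrays, was at least 1.36-fold higher (adjusted p = 0.0043). miR-139-5p rose by 0.74 ± 0.10 (1.67-fold, adjusted p = 0.0024), from 10.54 ± 0.10 (SD, n = 3) in Ctl+Ctl to 11.04 ± 0.14 (n = 3) in Ctl+AI, and from 10.63 ± 0.23 (n = 3) in NI+Ctl to 11.61 ± 0.11 (n = 3) in NI+AI. miR-153-3p rose by 0.72 ± 0.16 and miR-1949 by 0.68 ± 0.14. In the intestinal epithelium list 1 of 6 members rose, miR-375-3p of enteroendocrine cells, by 0.32 ± 0.09 (1.25-fold, adjusted p = 0.041). The list as a whole had a median of 0.19 and camera's adjusted p = 0.0833.

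The microRNAs most often tied to inflammation did not pass after adult TNBS: miR-155-5p stood at −0.31 ± 0.15 (SE, adjusted p = 0.29), miR-146a-5p at −0.27 ± 0.12 (adjusted p = 0.20), miR-21-5p at 0.15 ± 0.07 (adjusted p = 0.26) and miR-31a-5p at −0.34 ± 0.19 (adjusted p = 0.37). None of the 9 tested members of the inflammation-associated list passed over all probes or adjusted over the list alone, and the list's median was 0.03 (adjusted p = 0.947). Of the leukocyte list, with miR-223-3p of neutrophils and the blood cell microRNA miR-142-3p, 0 of 5 members passed (median −0.16, adjusted p = 0.886). The erythrocyte microRNA miR-451-5p stood at −0.62 (adjusted p = 0.11), and miR-210-3p, which hypoxia induces, stood at 0.18. The epithelial miR-200 family likewise had 0 of 5 calls, with a median of 0.12 (adjusted p = 0.492). Its member miR-200b-3p stood at 0.13, and the epithelial miR-192-5p and miR-194-5p at 0.05 and 0.00, although quantile normalization limits how far values at the upper end can differ. In limma's test of 389 probes, 31 passed an adjusted p of 0.05, of which 18 rose and 13 fell. None of these calls was left without normalization between arrays, where 0 probes passed and 15 had an unadjusted p under 0.05, and 15 probes passed with the arrays scaled by their 75th percentile, 19 among probes detected on all 12 arrays and 47 with array weights. The count was 20 without NI+Ctl array 1, 20 without NI+Ctl array 3 and 19 without NI+AI array 2, and of the 12 fits that each left out 1 array miR-375-3p kept its call in 1, miR-24-2-5p in 3, miR-145-5p in 4, miR-23a-3p in 5 and miR-10a-5p in 7. Over all settings tried, those without a call included, miR-133a-3p lay between −0.90 and −0.70, miR-143-3p between −0.56 and −0.44 and miR-379-5p between 0.71 and 1.19.

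**Figure D2:**
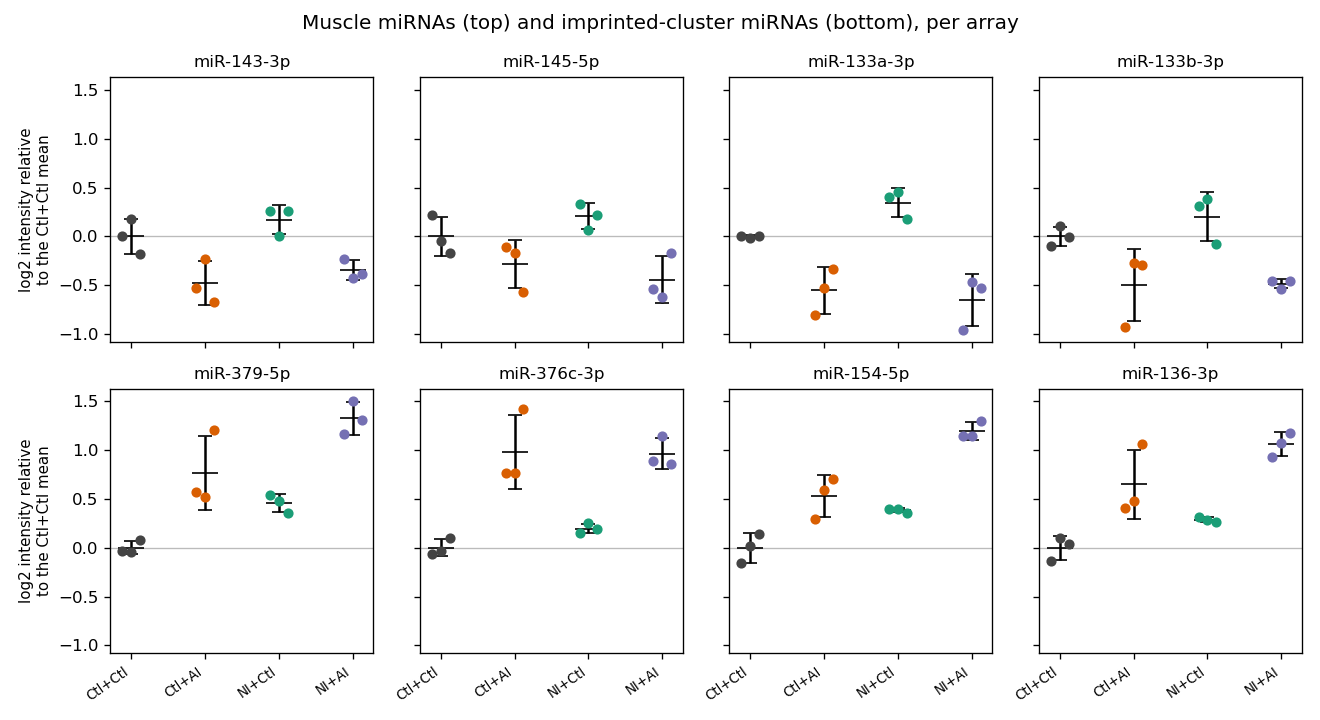
Log2 intensity of 8 microRNAs on each array relative to the Ctl+Ctl mean (y axes) by group (x axes); points are arrays, and bars give the mean ± SD of 3 arrays. The upper row shows 4 muscle microRNAs, such as miR-133a-3p with a mean of 9.71 in Ctl+Ctl and 9.06 in NI+AI, and the lower row 4 microRNAs of the imprinted region, such as miR-379-5p with 6.89 and 8.22.

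In rats given saline as neonates, adult TNBS (Ctl+AI against Ctl+Ctl, n = 3 each) left no single microRNA past the threshold. The smallest p belonged to miR-376c-3p, with 0.98 ± 0.17 on the log2 scale (SE, adjusted p = 0.0697). Next came miR-379-5p with 0.77 ± 0.18, miR-337-3p with 0.59 ± 0.15, miR-154-5p with 0.53 ± 0.13, miR-582-5p with 0.46 ± 0.12 and miR-136-3p, all with adjusted p between 0.21 and 0.22. miR-136-3p lay above the empty spots on 2 of 3 arrays of Ctl+AI and on none of Ctl+Ctl, so it was at least 1.08-fold higher. In Ctl+Ctl miR-379-5p lay above them on only some arrays. The muscle microRNAs miR-133a-3p and miR-143-3p stood at −0.55 ± 0.16 and −0.48 ± 0.15 (adjusted p = 0.22 and 0.29), and 2 of 8 members of the smooth muscle and mesenchyme list fell when adjusted over the list alone. As a list they were shifted down, with a median of −0.38 and camera's adjusted p = 0.00059, and adjusted p = 0.0537 with an estimated correlation. The 5 members of the list described as acting on Cdh1 mRNA were all lower, with a median of −0.30 (adjusted p = 0.0116, and adjusted p = 0.120 with an estimated correlation), as were the 9 of miR-17-92 and its paralogs, which promote proliferation, with a median of −0.21 (adjusted p = 0.0208, and adjusted p = 0.324 with an estimated correlation). Without normalization between arrays the medians of these lists were 0.16 and 0.27, the Cdh1 list still passing as shifted down relative to the other probes, and no member of either passed over all probes or adjusted over the list alone. Limma called 0 of 389 probes, and 31 had an unadjusted p under 0.05. The count was 4 in the deposited value table and 2 without Ctl+AI array 2.

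In rats that had TNBS as neonates, the second TNBS (NI+AI against NI+Ctl, n = 3 each) lowered muscle microRNAs, and single microRNAs of the imprinted region rose. miR-133a-3p fell by 1.00 ± 0.16 on the log2 scale (SE; 1.99-fold, adjusted p = 0.0089), from 10.06 ± 0.14 to 9.06 ± 0.27 (SD, n = 3). miR-199a-5p of fibroblasts and other mesenchymal cells fell by 0.87 ± 0.19, miR-133b-3p by 0.69 ± 0.19 and miR-145-5p by 0.65 ± 0.17. Thus 4 of the 8 tested members of the smooth muscle and mesenchyme list fell, 5 when adjusted over the list alone, and all 8 were lower, with a median of −0.59 (camera's adjusted p = 0.00016, and adjusted p = 0.036 with an estimated correlation). The largest fall was that of miR-29b-3p, of a family that restrains collagen synthesis, by 1.37 ± 0.32 (2.58-fold, adjusted p = 0.029), and miR-653-3p fell by 1.15 ± 0.16, miR-10a-5p by 1.03 ± 0.26, miR-130a-3p by 0.86 ± 0.21 and miR-24-1-5p by 0.85 ± 0.21. miR-338-3p, above the empty spots on all 3 arrays of NI+Ctl and on none of NI+AI, was at least 1.5-fold lower (adjusted p = 0.019). miR-139-5p rose by 0.98 ± 0.14 (1.97-fold, adjusted p = 0.0057). Of the imprinted region, miR-541-5p rose by 0.87 ± 0.21, miR-379-5p by 0.87 ± 0.18, miR-154-5p by 0.81 ± 0.13, miR-136-3p by 0.77 ± 0.17 and miR-376c-3p by 0.77 ± 0.17. miR-3596a and miR-153-3p rose by 0.91 ± 0.18 and 0.85 ± 0.23. Limma called 30 of 389 probes, 15 up and 15 down (9 and 15 with cyclic loess, 17 and 11 with 75th percentile scaling, and 0 without normalization, where 43 had an unadjusted p under 0.05). It called 71 with array weights and 15 among probes detected on all 12 arrays. The count was 2 without NI+Ctl array 1, 18 without NI+Ctl array 2, 6 without NI+Ctl array 3 and 4 without NI+AI array 2, and miR-145-5p, miR-133b-3p and miR-153-3p kept their calls in 4, 3 and 3 of the 12 fits that each left out 1 array.

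Whether the response to adult TNBS differed with neonatal treatment was tested as an interaction. The blood cell microRNAs miR-142-3p and miR-142-5p stood at −1.74 ± 0.51 and −1.18 ± 0.38 on the log2 scale (SE), as the difference between the response of TNBS-treated and of saline-treated neonates. For miR-142-3p the group means were 10.03 ± 0.38 (SD, n = 3) in Ctl+Ctl, 10.50 ± 0.54 (n = 3) in Ctl+AI, 9.32 ± 0.51 (n = 3) in NI+Ctl and 8.06 ± 0.53 (n = 3) in NI+AI. All 5 members of the leukocyte list had a negative interaction, with a median of −0.98, and 2 fell when adjusted over the list alone. The list was shifted down at the preset correlation (camera's adjusted p = 0.0104), but did not pass with the estimated correlation of 0.39 (adjusted p = 0.338). The others with the smallest p were miR-193-3p at −0.73 ± 0.19, miR-29a-5p at −0.83 ± 0.24, miR-29b-3p at −1.48 ± 0.45 and miR-547-5p at 1.01 ± 0.32, all with an adjusted p of 0.61. The smooth muscle and mesenchyme list had a median of −0.22 (adjusted p = 0.0673) and the miR-29 family of −0.30 (adjusted p = 0.0673). Limma called 0 of 389 probes, and 21 had an unadjusted p under 0.05. The median standard error of the interaction was 0.28.

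Neonatal TNBS, averaged over both adult treatments (6 arrays against 6), was followed by lower signals of 3 of 5 leukocyte microRNAs and 2 of 3 of the miR-29 family in the adult colon. miR-142-3p fell by 1.58 ± 0.26 on the log2 scale (SE; 2.98-fold, adjusted p = 0.0032), miR-223-3p by 1.64 ± 0.46 (3.12-fold, adjusted p = 0.026) and miR-142-5p by 0.70 ± 0.19 (1.63-fold, adjusted p = 0.021). These were 3 of the 5 members of the leukocyte list, over all probes and adjusted over the list alone, and the list's median was −0.70 (camera's adjusted p = 0.0412, adjusted p = 0.0523 with cyclic loess, and adjusted p = 0.670 with an estimated correlation). miR-29b-3p fell by 1.08 ± 0.23 and miR-29c-3p by 0.62 ± 0.10 (adjusted p = 0.0083 and 0.0031), 2 of 3 members of the miR-29 family, whose median was −0.62 (adjusted p = 0.0289, and adjusted p = 0.442 with an estimated correlation). The list call of the miR-29 family was lost with every other scaling tried, and its median was negative with each. let-7e-5p fell by 1.27 ± 0.25 and miR-98-5p by 0.58 ± 0.18, 2 of 8 members of the let-7 family, whose median was −0.06 (adjusted p = 0.350), or 0.04 with 75th percentile scaling. miR-126a-5p of endothelium was at least 4.70-fold lower (adjusted p = 0.0026), while its partner arm miR-126a-3p stood at 0.02 ± 0.11. The miR-126a-5p probe lay above the empty spots on all 6 arrays of saline-treated neonates, on 2 of 3 arrays of NI+Ctl and on 0 of 3 of NI+AI. The other large falls, of miR-377-3p by 2.47 ± 0.58, of miR-6216 by 2.22 ± 0.50, of miR-664-1-5p by 1.82 ± 0.46, of miR-365-3p by 1.53 ± 0.37 and of miR-668 by 1.36 ± 0.31, came with wide spreads in the saline groups, such as 10.80 ± 1.78 (SD, n = 3) for miR-377-3p in Ctl+Ctl.

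The rises with neonatal TNBS included miR-18a-5p, miR-93-5p and miR-92a-3p of miR-17-92 and its paralogs. miR-18a-5p rose by 1.00 ± 0.14 on the log2 scale (SE; 2.00-fold, adjusted p = 0.0015), miR-93-5p by 0.69 ± 0.13 and miR-92a-3p by 0.65 ± 0.14. Of the 9 members 4 rose and 1, miR-19a-3p, fell by 0.69 ± 0.23, and the list's median was 0.21 (adjusted p = 0.505), or −0.45 without normalization between arrays. In the inflammation-associated list 2 of 9 members rose, miR-34a-5p, a target of p53, by 0.63 ± 0.09 (1.55-fold, adjusted p = 0.0015) and miR-147 by 0.70 ± 0.15. The median of that list was 0.16 (adjusted p = 0.565), or −0.12 with 75th percentile scaling and −0.72 without normalization. miR-328a-3p rose by 1.01 ± 0.12 (2.02-fold, adjusted p = 0.0015), miR-378a-5p by 0.80 ± 0.12, miR-1843-3p by 1.07 ± 0.24, miR-3596c by 1.03 ± 0.21, miR-547-5p by 0.77 ± 0.16 and miR-671 by 0.74 ± 0.20. Of the microRNAs described as acting on Cdh1 mRNA, miR-92a-3p rose, miR-9a-5p fell by 0.31 ± 0.09 and 3 did not pass (median 0.00, adjusted p = 0.737). Of the neuronal list miR-128-3p rose by 0.39 ± 0.11 while miR-218a-5p and miR-9a-5p fell (median −0.11, adjusted p = 0.531), and of the list described as acting on epithelial permeability 1 of 5 fell, miR-223-3p (median −0.10, adjusted p = 0.350, with a median of 0.03 under cyclic loess). The miR-200 family had 0 of 5 calls and a median of 0.02 (adjusted p = 0.846), or −0.24 without normalization. The smooth muscle and mesenchyme list had 0 of 8 calls and a median of 0.05 (adjusted p = 0.769), which was negative with every other scaling tried, such as −0.10 with 75th percentile scaling.

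In limma's test 99 of 389 probes passed for neonatal TNBS, with 69 up and 30 down. The balance of rises and falls followed the scaling: it was 36 up and 38 down with cyclic loess, 35 and 45 in the deposited value table, 11 and 54 with 75th percentile scaling, and without normalization between arrays 0 up and 36.8% of the 389 probes down. The median of all tested probes was 0.07 with quantile normalization, −0.18 with 75th percentile scaling and −0.79 without normalization, so a rise is one relative to the bulk of the probes. Of the 12 fits that each left out 1 array, miR-98-5p kept its call in 3, miR-19a-3p and miR-9a-5p in 4 each, and miR-223-3p and miR-128-3p in 6 each. The arrays compared also differed in spike-in controls: 27 of 43 spike-in probes were lower on arrays of TNBS-treated neonates and 0 were higher (limma, adjusted p under 0.05; 29 had an unadjusted p under 0.05). With the spike-in mismatch ratio of each array as a covariate, a fit chosen after seeing the data, 68 microRNAs passed, 34 up and 34 down, among them 19 of the 99.

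Neonatal TNBS alone (NI+Ctl against Ctl+Ctl, n = 3 each) left no microRNA past the threshold. The smallest p belonged to miR-185-5p, with 0.70 ± 0.12 on the log2 scale (SE, adjusted p = 0.056), which stood at 9.63 ± 0.14 (SD, n = 3) in Ctl+Ctl and 10.33 ± 0.11 (n = 3) in NI+Ctl. miR-328a-3p stood at 0.87 ± 0.18, miR-151-3p at 0.61 ± 0.13, miR-34a-5p at 0.59 ± 0.12, miR-425-3p at 0.72 ± 0.17 and miR-378b at 0.61 ± 0.14, with adjusted p between 0.056 and 0.075. miR-126a-5p stood at −2.06 ± 0.52 (adjusted p = 0.077), and when adjusted over the list alone it was the 1 of 2 endothelial microRNAs that fell. Adjusted over the list alone, 2 of 9 members of the inflammation-associated list rose, miR-34a-5p and miR-147, and 1 of 3 members of the miR-29 family fell. No list passed camera's test. Limma called 0 of 389 probes, and 82 had an unadjusted p under 0.05. Single choices moved this count, which was 71 with array weights, 17 without Ctl+Ctl array 3, 9 without the filter on dim probes, 3 among probes detected on all arrays, 1 without Ctl+Ctl array 1, 1 in the deposited value table and 1 without normalization. It also rose above 17 with the spike-in mismatch ratio as a covariate, a fit chosen after seeing the data. Among the 43 spike-in probes 0 passed in this comparison, and 15 had an unadjusted p under 0.05.

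Among rats given TNBS as adults, those with neonatal TNBS (NI+AI against Ctl+AI, n = 3 each) had lower signals of 2 of 5 leukocyte microRNAs and 2 of 3 of the miR-29 family. miR-142-3p fell by 2.45 ± 0.36 on the log2 scale (SE; 5.45-fold, adjusted p = 0.0046), and miR-142-5p by 1.30 ± 0.27 (2.46-fold, adjusted p = 0.012). Thus 2 of 5 leukocyte microRNAs fell, 3 when adjusted over the list alone, with a median of −1.30 (camera's adjusted p = 0.00829, and adjusted p = 0.394 with an estimated correlation). miR-29b-3p fell by 1.82 ± 0.32 (3.53-fold), from 12.03 ± 0.35 to 10.21 ± 0.26 (SD, n = 3), and miR-29c-3p by 0.77 ± 0.14, so that 2 of 3 members of the miR-29 family fell (median −0.77, adjusted p = 0.00829, and adjusted p = 0.358 with an estimated correlation). That list call was lost with every other scaling tried, with a negative median in each. miR-126a-5p was at least 5.31-fold lower (adjusted p = 0.0087). miR-377-3p fell by 2.93 ± 0.82, miR-664-1-5p by 2.26 ± 0.65, miR-365-3p by 1.99 ± 0.52, miR-668 by 1.58 ± 0.44 and let-7e-5p by 1.47 ± 0.35. Of miR-17-92 and its paralogs 4 of 9 rose and 0 fell, with miR-18a-5p at 1.33 ± 0.20, miR-93-5p at 0.86 ± 0.18, miR-92a-3p at 0.85 ± 0.20 and miR-20a-5p at 0.49 ± 0.14 (median 0.49, adjusted p = 0.343, or a median of −0.89 without normalization). Adjusted over the list alone, 4 rose and 1 fell. miR-3596c, miR-1843-3p, miR-547-5p, miR-328a-3p, miR-671, miR-378a-5p and miR-3596a rose by between 0.94 and 1.41. Limma called 55 of 389 probes, 33 up and 22 down, against 15 and 19 with cyclic loess, 5 and 29 with 75th percentile scaling, 18 and 35 in the deposited value table, and without normalization 0 up and 57.3% of the 389 probes down. The count was 23 in a fit to only these groups and 36 with the spike-in mismatch ratio as a covariate, chosen after seeing the data. Of the spike-in probes 24 of 43 were lower in NI+AI, and the count of microRNAs was 24 without Ctl+AI array 1, 36 without Ctl+AI array 2, 30 without NI+AI array 1 and 22 without NI+AI array 2. Of the 12 fits that each left out 1 array, miR-20a-5p kept its call in 3, miR-664-1-5p in 5 and miR-377-3p in 6.

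With TNBS at both ages against neither (NI+AI against Ctl+Ctl, n = 3 each), 29 microRNAs fell, among them 2 of the leukocyte list, 2 of the miR-29 family and 2 of the smooth muscle and mesenchyme list. miR-142-3p fell by 1.97 ± 0.36 on the log2 scale (SE; 3.92-fold, adjusted p = 0.0044), miR-29b-3p by 1.71 ± 0.32 (3.26-fold, adjusted p = 0.0049), miR-199a-5p by 0.77 ± 0.19 and miR-133a-3p by 0.65 ± 0.16. miR-126a-5p was at least 4.18-fold lower (adjusted p = 0.010). miR-653-3p, with the smallest p of the comparison, fell by 1.51 ± 0.16 (2.85-fold, adjusted p = 5.2e-04), from 8.98 ± 0.16 to 7.47 ± 0.09 (SD, n = 3), miR-96-5p by 1.32 ± 0.19, let-7e-5p by 1.56 ± 0.35, miR-365-3p by 1.71 ± 0.52 and miR-668 by 1.53 ± 0.44. Of the lists, 2 of 8 smooth muscle and mesenchyme microRNAs fell, also when adjusted over the list alone, and all 8 were lower (median −0.47, camera's adjusted p = 0.0114, and adjusted p = 0.157 with an estimated correlation). The leukocyte list, with 2 of 5 fallen, and the miR-29 family, with 2 of 3, had medians of −0.87 and −0.57 and did not pass (adjusted p = 0.0784 and 0.071). The largest rises were those of miR-497-3p by 1.95 ± 0.61, which kept its call in 5 of the 12 fits that each left out 1 array, of miR-3596c by 1.65 ± 0.30, of miR-1843-3p by 1.60 ± 0.34, of miR-181a-2-3p by 1.39 ± 0.38, of miR-671 by 1.37 ± 0.28, of miR-379-5p by 1.33 ± 0.18, of miR-667-3p by 1.26 ± 0.26 and of miR-153-3p by 1.25 ± 0.23. Above the empty spots lay miR-379-5p and miR-153-3p on 1 of 3 arrays of Ctl+Ctl each, and miR-365-3p on 1 of 3 of NI+AI. miR-18a-5p rose by 1.13 ± 0.20 and miR-34a-5p by 0.74 ± 0.12. The epithelial miR-375-3p rose by 0.47 ± 0.12 (1.39-fold, adjusted p = 0.018), while 0 of 5 members of the miR-200 family passed (median 0.18, adjusted p = 0.646, or −0.11 without normalization). Of the microRNAs described as acting on Cdh1 mRNA only miR-9a-5p passed over all probes, falling by 0.60 ± 0.13, and 1 rose and 1 fell when adjusted over the list alone. Limma called 94 of 389 probes, 65 up and 29 down, against 37 and 35 with cyclic loess, 20 and 24 with 75th percentile scaling, 40 and 49 in the deposited value table, and 0 and 49 without normalization. The count was 150 with array weights and 52 in a fit to only these groups. Of the spike-in probes 16 of 43 were lower in NI+AI, and 60 microRNAs passed without Ctl+Ctl array 2 or without NI+AI array 2.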

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

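Of the tests reported here, those with the spike-in probes and their ratio, those with GC content and the correlation between muscle microRNAs were chosen only after the result was seen. A signal outside the main measurement stood out: 27 of the 43 spike-in control probes, which do not come from rats, were lower on the 6 arrays of TNBS-treated neonates than on the 6 of saline-treated neonates (limma, adjusted p under 0.05), and 0 were higher. The leukocyte list also stood out in the interaction at the preset correlation of 0.01 (camera's adjusted p = 0.0104). Its median interaction was −0.98 on the log2 scale, with 5 of 5 members lower and 0 past the threshold over all probes. With the correlation of 0.39 estimated for this list, camera's adjusted p was 0.338, so a difference in response is not established.

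The neonatal main effect, with 99 microRNAs past the threshold, was weighed against the arrays' hybridization. Removing each array's trend with GC content left 79 of the 99 past the threshold in the same direction, which argues against GC content as the whole cause. Fold change and GC content were nevertheless correlated across probes (rho 0.14, permutation p = 0.0051, probes not being independent). The median GC content was 50% among the called rises and 40.0% among the called falls, so GC content as part of the cause stays open. With the spike-in mismatch ratio as a covariate 68 probes passed, among them 19 of the 99 in the same direction. All 99 kept their sign, the median size of their differences went from 0.55 to 0.42 and the median standard error from 0.12 to 0.18. Calls thus ended through both smaller differences and wider errors. The 99 were picked for their differences without the covariate, so that choice alone can make them shrink in another fit. Over all 389 tested probes the median size went from 0.26 to 0.32, and 290 kept their sign. The ratio differed by −2.49 between neonatal treatments. The 6 arrays of each did not overlap, but the nearest were close, at −7.50 (NI+AI array 3) and −7.45 (Ctl+Ctl array 2). With no slide or date in the files, a batch that follows neonatal treatment cannot be told apart from the treatment. Changes predicted from arrays within groups correlated with the neonatal fold changes with rho 0.14 (permutation over 1296 orders, p = 0.444). Of the 99, 72 had the predicted sign. These values leave open whether stringency, or the array background that also enters the ratio, was the whole cause, part of it or no cause. An effect of neonatal TNBS stays open as well.

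The fall of muscle microRNAs after adult TNBS had a median of −0.48 over the 8 members of the smooth muscle and mesenchyme list, all lower. The median was −0.49 with the spike-in ratio as a covariate and −0.47 after the GC trend was removed. Neither correction could move it far. The ratio differed by 0.16 between adult treatments (exact permutation test, p = 0.866), and fold change and GC content had rho 0.07 across probes (permutation p = 0.17). It is these values, rather than the corrected medians, that argue against either as the cause. A different amount of muscle in the dissected samples may also lower these microRNAs. Between arrays of the same group 5 muscle microRNAs, whose changes ran from −0.77 for miR-133a-3p to −0.37 for miR-1-3p, had a mean correlation of 0.0889, at the 74.05th percentile of 10000 random sets (median −0.01). That leaves open whether the dissected amount or expression within muscle cells differed, and the design offers adult TNBS as an untested biological explanation for both.

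Other splits of the arrays were counted for each comparison. For neonatal TNBS 1 of 100 drawn splits, the real one, gave as many as 99 calls (highest other 20). For adult TNBS 2 of 100, the real one among them, gave as many as 31 (highest other 52). Both shares lie under 0.05, but this does not exclude chance. For adult TNBS another split of the same arrays gave more calls than the real one. For the interaction limma made 0 calls (21 probes had an unadjusted p under 0.05), so that 100 of 100 splits necessarily gave as many (highest other 11) and the splits say nothing of it. The 5 comparisons of 3 arrays with 3 have only 10 splits, too few for a share under 0.05. The real and highest other counts were 94 and 1 for NI+AI against Ctl+Ctl, 55 and 0 for NI+AI against Ctl+AI, 30 and 0 for NI+AI against NI+Ctl, 0 and 0 for NI+Ctl against Ctl+Ctl, and 0 and 75 for Ctl+AI against Ctl+Ctl. The split with 75 calls set Ctl+Ctl array 1, Ctl+AI array 1 and Ctl+AI array 3 against the others and points to a structure of the samples: the lowest spike-in ratio of those 3 was −5.88 and the highest of the others −6.53. Of the 75, 9 were also called for neonatal TNBS, whose saline side holds the same arrays, against 19.1 expected of independent lists. Of these 9, 7 had the opposite sign, as a common tie to the ratio would give. No reference for lists that share arrays was computed, so neither the overlap nor the signs decide on that tie.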

How the results depend on the processing

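The tests with the spike-in covariate, without 2 arrays, with the GC trend removed and of lists under settings other than an estimated correlation were chosen only after the result was seen. Of 117 calls of named microRNAs, 20 were kept in every planned setting and every fit without 1 array, and 56 when the setting without normalization was left aside. Single settings kept 92 with cyclic loess, 76 with 75th percentile scaling, 70 with the spike-in covariate and 40 without normalization. A fit to only the groups compared kept 49 of the 70 calls it could test, and leaving out 1 array kept between 69 and 107. No paired analysis was possible because the numbers in the titles are not shared between groups. A slide or scan block was not run, since the files give none, and a fit to only the groups compared has no separate value for main effects and the interaction. Signal over background limits what can be said of probes near the empty spots. Counts not given here stayed within 1.5 times of those reported. Except where fewer probes or arrays entered the test, the cause was not tested.

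With cyclic loess the count of NI+AI against Ctl+AI was 34. With 75th percentile scaling NI+AI against Ctl+Ctl had 44, NI+AI against Ctl+AI 34, adult TNBS 15 and neonatal TNBS 65. Without normalization NI+Ctl against Ctl+Ctl had 1, NI+AI against Ctl+Ctl 49, NI+AI against Ctl+AI about 2.2e+02 (57.3% of the 389 probes), and NI+AI against NI+Ctl and adult TNBS 0 (limma, 43 and 15 at unadjusted p under 0.05). In the deposited value table Ctl+AI against Ctl+Ctl had 4 and NI+Ctl against Ctl+Ctl 1. Ctl+AI against Ctl+Ctl had 1 with no background correction, with subtraction and a floor, with an offset of 16, with the trended robust fit and with array weights. NI+Ctl against Ctl+Ctl had 9 without the filter on dim probes. Among probes detected on all 12 arrays it had 3, NI+AI against NI+Ctl 15 and adult TNBS 19. With array weights it had 71, NI+AI against Ctl+Ctl 150, NI+AI against NI+Ctl 71 and adult TNBS 47. Fitted to the groups compared, NI+AI against Ctl+Ctl had 52 and NI+AI against Ctl+AI 23. With the spike-in covariate NI+Ctl against Ctl+Ctl had 22 and NI+AI against Ctl+AI 36. NI+Ctl against Ctl+Ctl had 2 without Ctl+Ctl array 1 and Ctl+AI array 1, and 1 with the GC trend removed. Of the list calls, 11 as reported, 21 were made with 75th percentile scaling, 17 without the filter, 5 with the covariate and 2 with an estimated correlation.

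Leaving out each array in turn gave counts of 0 to 2 for Ctl+AI against Ctl+Ctl (2 without Ctl+AI array 2), 0 to 17 for NI+Ctl against Ctl+Ctl (1 without Ctl+Ctl array 1, 17 without Ctl+Ctl array 3), 60 to 90 for NI+AI against Ctl+Ctl (60 without Ctl+Ctl array 2 or NI+AI array 2), 22 to 72 for NI+AI against Ctl+AI (24 without Ctl+AI array 1, 36 without Ctl+AI array 2, 30 without NI+AI array 1, 22 without NI+AI array 2), 2 to 42 for NI+AI against NI+Ctl (2, 18 and 6 without NI+Ctl arrays 1, 2 and 3, 4 without NI+AI array 2), 0 for the interaction (limma, 21 at unadjusted p under 0.05 with all arrays), 19 to 36 for adult TNBS (20 without NI+Ctl array 1 or 3, 19 without NI+AI array 2), 68 to 100 for neonatal TNBS and 8 to 16 for the lists.

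Most reversals came without normalization, which by its construction keeps differences in overall signal between arrays and put the median of all probes at −0.79 for neonatal TNBS, −1.23 for NI+AI against Ctl+AI and −0.775 for NI+AI against Ctl+Ctl. With 75th percentile scaling the value of miR-128-3p, neonatal TNBS main effect, was −0.0321. Without normalization, for NI+AI against Ctl+Ctl, miR-18a-5p stood at −0.0495, miR-34a-5p at −0.23, miR-128-3p at −0.45 and miR-93-5p at −0.32. For NI+AI against Ctl+AI, miR-3596c stood at −0.0699, miR-18a-5p at −0.32, miR-1843-3p at −0.26, miR-547-5p at −0.10, miR-328a-3p at −0.54, miR-671 at −0.63, miR-378a-5p at −0.78, miR-93-5p at −0.62, miR-92a-3p at −0.37, miR-34a-5p at −0.78, miR-20a-5p at −0.68 and miR-451-5p at −1.46. For neonatal TNBS, miR-328a-3p stood at −0.0419, miR-18a-5p at −0.0891, miR-378a-5p at −0.31, miR-671 at −0.37, miR-147 at −0.32, miR-93-5p at −0.21, miR-92a-3p at −0.0583, miR-34a-5p at −0.40, miR-128-3p at −0.64 and miR-451-5p at −0.89. Unlike the others, miR-451-5p was not called as reported in either comparison, and other uncalled microRNAs that changed sign are not listed.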

Other observations

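The genomic clusters as lists, their values with the spike-in covariate and with the GC trend removed, and the values of the mesenchymal microRNAs are tests chosen only after the result was seen. Of 12 clusters of neighbouring microRNA genes, 3 passed camera's test after adult TNBS at the preset correlation and none with an estimated correlation. In the cluster between Mir379 and Mir3072, part of the imprinted region between Dlk1 and Dio3 that is transcribed from the maternal chromosome, 6 of 31 tested microRNAs rose (7 when adjusted over the list alone), 22 were higher and 9 lower, and the median was 0.24 on the log2 scale (camera's adjusted p = 1.9e-04 over 12 clusters, and adjusted p = 0.223 with an estimated correlation). In the adjoining cluster between Mir770 and Mir370, 5 of 11 rose and 7 were higher, with a median of 0.37 (adjusted p = 0.0011, and adjusted p = 0.223 with an estimated correlation). Among probes detected on all 12 arrays the medians were 0.25 and 0.22 and neither cluster passed (adjusted p = 0.305 for both). In the cluster between Mir24-2 and Mir181d, 3 of 7 fell and all 7 were lower, with a median of −0.31 (adjusted p = 2.8e-04, and adjusted p = 0.114 with an estimated correlation). Its called members were miR-23a-3p, miR-24-2-5p and miR-27a-3p, which fell by 0.31 ± 0.07 (SE, adjusted p = 0.026).

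These 3 clusters also passed at the preset correlation in both comparisons of adult TNBS with adult saline, which share their arrays with the main effect. In Ctl+AI against Ctl+Ctl limma called 0 of the 389 probes, and 31 had an unadjusted p under 0.05. The medians were 0.16 for Mir379 to Mir3072 (adjusted p = 0.0030), 0.23 for Mir770 to Mir370 (adjusted p = 0.0035) and −0.23 for Mir24-2 to Mir181d (adjusted p = 0.0035), the last 0.14 without normalization between arrays. The cluster between Mir17 and Mir92a1 passed there as well, with a median of −0.17 (adjusted p = 0.037), or 0.26 without normalization. With an estimated correlation these 4 had an adjusted p = 0.214 each. In NI+AI against NI+Ctl the cluster between Mir379 and Mir3072 had 5 rises and a median of 0.21 (adjusted p = 5.9e-04, and adjusted p = 0.357 with an estimated correlation), or −0.09 without normalization between arrays. The cluster between Mir770 and Mir370 had 4 rises and a median of 0.32 (adjusted p = 0.0020, and adjusted p = 0.298 with an estimated correlation), or −0.11 without normalization. The cluster between Mir24-2 and Mir181d had 1 fall and a median of −0.46 (adjusted p = 8.4e-04, and adjusted p = 0.160 with an estimated correlation). In the interaction none of the 3 passed (adjusted p = 0.246, 0.269 and 0.246). In NI+AI against Ctl+Ctl the cluster between Mir24-2 and Mir181d had a median of −0.38 (adjusted p = 0.0417, and adjusted p = 0.503 with an estimated correlation). The 2 clusters of the imprinted region did not pass there, with medians of 0.31 and 0.54 (adjusted p = 0.0881 for both), or −0.59 and −0.40 without normalization. With neonatal TNBS the region did not move in 1 direction. Between Mir379 and Mir3072, 5 microRNAs rose and 3 fell, and between Mir770 and Mir370, 3 rose and 1 fell (camera's adjusted p = 0.586 for both). In NI+AI against Ctl+AI, 2 rose and 3 fell in the former and 1 rose and 0 fell in the latter (adjusted p = 0.544 for both).

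The rise of the Mir379 to Mir3072 cluster after adult TNBS was weighed against 3 explanations. With the spike-in ratio as a covariate its median was 0.23, and after the GC trend was removed it was 0.22, both still shifted up in camera's test at the preset correlation. As for the muscle list, neither correction could move the median far. The ratio hardly differed between adult treatments, and across probes fold change hardly followed GC content. It is this that argues against either as the cause. More mesenchymal cells in the sample could raise miR-199a-3p, miR-199a-5p and miR-214-3p, which stood at −0.10, −0.49 and −0.30, a median of −0.30. These belong to the smooth muscle and mesenchyme list, all tested members of which had already been seen to be lower. Their direction was thus known beforehand, and a fall shared with that list could hide such a rise, so these values do not exclude this explanation. A candidate explanation that stays open is joint regulation of the imprinted region in the injured colon, as a hypothesis found and tested on the same arrays, and these data hold no measure of its host transcripts.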
